A study of Homo sapiens with 33 samples.

How the data were processed

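HEK293T, an immortalised human embryonic kidney line, was measured by 3 methods. RNA-seq of polyadenylated RNA covered 15 libraries in 5 groups. All groups received 10 nM of an siRNA against hnRNPG, the RNA-binding protein made by the gene RBMX, together with 24 ng/mL of plasmid, and RNA was collected 68 h later. The plasmids were an empty Flag vector (NCV), wild-type hnRNPG (WT), or hnRNPG with a mutated RNA recognition motif (RRMmut), first RGG region (RGG1mut) or second RGG region (RGG2mut). PAR-CLIP, in which a thiouridine-labelled RNA is crosslinked by ultraviolet light to the protein that binds it, was done for hnRNPG in the chromatin fraction and covered 6 libraries. The cells had 200 µM 4-thiouridine for 14 h. ChIP-seq, which recovers the DNA bound by a protein, covered 12 samples. These were RNA polymerase II (Pol II), its serine 2-phosphorylated form (S2P), its serine 5-phosphorylated form (S5P) and an input sample, each after a control siRNA (siC) or 1 of 2 hnRNPG siRNAs (sihnG3, sihnG4) at 20 nM for 48 h. The siRNA of the RNA-seq has the catalogue number of sihnG3. The 3 RNA-seq libraries of a group are called biological replicates by the series, which does not say whether they came from separate cultures. The p-values of single genes and exons therefore measure the spread between these libraries. Those of gene lists set the members of a list against the other genes, and those of PAR-CLIP rest on random draws of exons.

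The deposited RNA-seq tables, with genes and exons apart for each comparison with WT, give a signal for each library. Per the file headers and the values, this signal is a number of reads divided by a DESeq2 size factor for the library. Reads were aligned with STAR, counted with featureCounts and compared with DESeq2 on GRCh37/hg19, per the submitters' processing notes, which give no versions for these tools. The library kit was stranded per the labels' protocols, but the strand setting of the counting is not given. The deposited tables also give the authors' log2 fold change against WT with its standard error, and the authors' p-value and adjusted p. The deposited PAR-CLIP list holds sites pooled over the 6 libraries, made with STAR, Bowtie and bedtools per the submitters' processing notes. Its deposited score is 0 for every site, so only positions and strand were used. ChIP-seq peaks were called with MACS2 after Trim Galore, Bowtie2 2.2.6, SAMtools and bedtools on hg19, with dm6 for the Drosophila spike-in, per the submitters' processing notes. Each deposited peak has a score, a ratio (fold over the caller's local background) and −log10 of its p and q, as read from the layout and values of the lists. The peak threshold and the use of spike-in and input are not stated in the labels.

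Every signal was a whole multiple of 1 step per library and table within a tolerance of 0.01, so reads were recovered. The reads of the WT libraries were equal in all 4 tables (0 unequal of 19254 shared genes and 161412 shared exons). Recovered gene reads per library ran from 75930570 to 103580398. Between libraries of 1 group, log2 values correlated at 0.988 to 0.997, and the differences exceeded counting error (chi-square per gene from 5.03 to 130 over 15 pairs of libraries). Exon starts were read as 1-based, since this made 1789 of 15939 gene spans equal to their RefSeq length (GRCh38.p14 lengths, used for lengths only) and a 0-based reading 65. Coordinates are hg19, as the tables give them, and a gene's span is that of its listed exons. For PAR-CLIP and ChIP, genes were kept with 1 locus and a span of at most 1.5 times the RefSeq length, a limit set after overlong spans were seen among the genes with the most sites. This kept 15888 of 17097 symbols, while 42 had several loci, 1116 had no RefSeq length and 51 were too long.

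Genes and exons were compared with WT within each table by limma-trend (limma 3.58.1, R 4.3.3) on log2(signal + 1), with a mean of at least 10 and Benjamini-Hochberg adjusted p under 0.05. Exon usage was compared by limma's diffSplice, which sets the change of an exon against the mean change of the other exons of its gene, in genes with at least 2 exons. The mutants were compared with NCV in 1 limma fit of all 15 libraries on recovered reads scaled together. Lists of genes were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. Of 25 fixed lists, 1 (mitochondrially encoded mRNAs) had under 3 measured members and was not tested. Markers of epithelial and liver cells were tested in NCV and RGG1mut, the comparisons with enough measured members. PAR-CLIP sites of either strand within 250 nt of exons with a called usage change were counted. They were set against 10000 random sets of tested exons matched on deciles of expression and length, with a one-sided permutation p. ChIP lists, with 1 library each, were described without a test, with exact 95% confidence intervals for shares of peaks. These intervals cover counting error only. Designs, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes RBMX, then up to 12 rises and 12 falls per gene comparison among genes past the threshold with a symbol, a mean of at least 50 and groups that do not overlap. It takes up to 4 members per list by lowest p, 5 rises and 5 falls in usage with a mean of at least 50, the 3 longest siC peaks per antibody, and the 10 genes with the most PAR-CLIP sites.

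The methods were tested on simulated data made from the NCV and WT libraries. Of 19330 simulated genes, limma-trend found 28% of those changed 1.5-fold, 72% of 2-fold, 93.8% of 4-fold and 100% of 8-fold, with 17 false among 161 calls. edgeR (4.0.16) made 17 false of 164 calls and DESeq2 (1.42.0) 60 of 222. The list test called the 1 raised list and 0 others. The simulated genes were drawn independently of each other, so this check cannot tell how the test does on lists of correlated genes. The usage test failed this check over 160903 exons. With a spread for each exon, 328 of its 454 calls were false, and with a spread set by the mean alone 41 of 151. Precision weights lowered this to 119 of 241 and 13 of 136, and a variance for each exon to 5 of 82 and 16 of 135, while edgeR made 80 of 211 and 14 of 164. With a spread for each exon, the usage test found 44% of 2-fold and 84% of 4-fold changes, precision weights 44 and 82%, a variance for each exon 2 and 60%, and edgeR 28 and 80%. The designed test was kept, and counts from the other versions stand beside each usage count. The PAR-CLIP test gave p under 0.05 in 7% of 200 simulated sets without enrichment.

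Alternatives included a mean of at least 50, pseudocounts 0.5 and 5, other scalings, edgeR, DESeq2, 1 fit of all 15 libraries, each library left out in turn, other PAR-CLIP distances, and stricter or merged peaks. Alternatives chosen after the data were seen were 1 surrogate factor of the libraries (sva 3.50.0), the weighted and exon-wise usage tests, and PAR-CLIP counts on the gene's strand, without RBMX, with weighted calls or matched also on gene expression. Removing the filter of 10 changed nothing, because the deposited tables list only genes and exons above it. Site counts by upper score were not run, since every score is 0. Other software was data.table (1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Among the longest peaks, a locus on the X chromosome was left out, because levels tied to sex are not shown for human cells.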

Results

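Human HEK293T cells were measured by RNA-seq (15 libraries), PAR-CLIP (6 libraries, pooled by the authors into 1 list of sites) and ChIP-seq (12 samples, of which 3 were inputs). In the RNA-seq, cells given an siRNA against hnRNPG, made by the gene RBMX, received the empty vector (NCV), wild-type hnRNPG (WT) or hnRNPG mutated in its RNA recognition motif (RRMmut) or in 1 of 2 arginine and glycine rich regions (RGG1mut, RGG2mut), with 3 libraries each. Gene reads per library were 85397426, 81920754 and 96169762 in NCV and 80612317, 75930570 and 103580398 in WT. They were 78184776, 83890604 and 97908024 in RRMmut, 92485810, 86953173 and 93380568 in RGG1mut, and 86427427, 86346467 and 98418901 in RGG2mut. Levels below are DESeq2-normalised reads per library, given as mean ± SD with n = 3 per group, scaled within each comparison.

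RBMX, the targeted gene (NM_001164803, hg19 chromosome X, 135951353 to 135962939), was checked first. Its level was 22112 ± 1309 in NCV against 404180 ± 15624 in WT, 18.3-fold lower (log2 −4.19, SE 0.06, limma adjusted p = 1.5e-06). The NCV libraries were at 21506, 21215 and 23614 and the WT libraries at 389620, 402220 and 420690. RRMmut had 200330 ± 7694 against 399850 ± 16453 in WT, 2.00-fold lower (log2 −0.997, SE 0.06, adjusted p = 0.0099, lower in 3 of 3 libraries). RGG1mut had 309230 ± 11519 against 407250 ± 14790 (log2 −0.40, SE 0.05, adjusted p = 0.65), and RGG2mut 311690 ± 28566 against 406410 ± 16395 (log2 −0.39, SE 0.07, adjusted p = 0.96). In both, all 3 libraries lay below all 3 of WT. Over all genes RBMX passed in neither by limma or edgeR, while DESeq2 called it in RGG1mut (the authors' adjusted p = 0.0076). RBMX reads, which can include those from the plasmids, were unequal among the groups compared below. The lower level in NCV lay in the inner exons, for example at 135957417 to 135957542 (2593 ± 228 against 81437 ± 4208, log2 −4.98, adjusted p = 5.8e-06). The last exon at 135951353 to 135952576 (2643 against 3123, log2 −0.24), the exon at 135954427 to 135954504 (528 against 593, −0.16) and the first at 135962756 to 135962939 (1504 against 1384, log2 0.12) did not pass. In the mutants these outer exons differed from WT by log2 0.12 to 0.26. All groups received the siRNA. As far as the outer exons report it, these values argue against a fall of the cell's own RBMX message as the source of the difference. Unequal plasmid reads over the inner exons could give it.

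**Figure D1:**
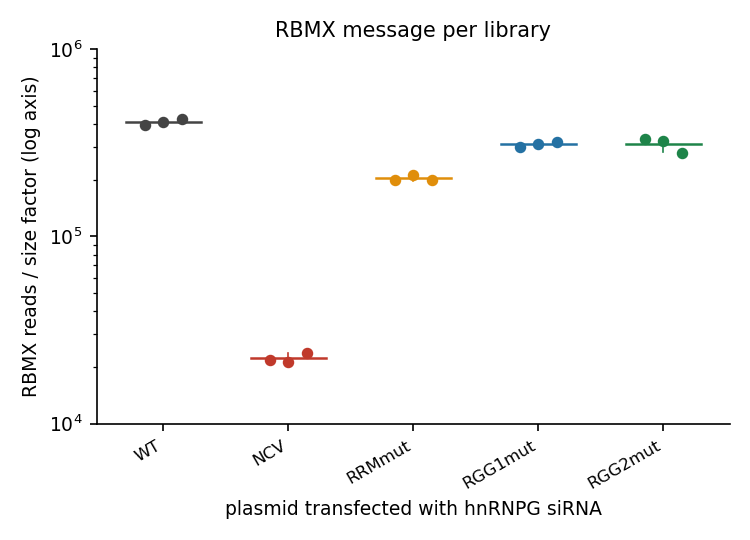
Normalised RBMX reads (log axis) in each library of the 5 groups, with group means and SD. NCV lies 18.3-fold below WT, RRMmut 2.00-fold below, and the RGG mutants in between RRMmut and WT.

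The first comparison asked which transcripts changed when no hnRNPG was supplied (NCV against WT). Fell and rose mean lower and higher in NCV than in WT. The RNA-seq has no group without the hnRNPG siRNA. A gene that fell in NCV therefore cannot be told from one raised by the hnRNPG supplied in WT, nor a rise from the reverse. Beside RBMX, most genes called by limma fell, and most had few reads. FAM71F1 (NR_104243, chromosome 7, 128371154 to 128371797) fell from 102 ± 6.16 to 13.7 ± 0.80, 7.05-fold (log2 −2.82, SE 0.14, limma adjusted p = 0.0015). LEXM (NM_152607) fell from 203 ± 17.8 to 33.4 ± 2.87 (log2 −2.57, SE 0.13, adjusted p = 0.0015) and FAM81B (NM_152548) from 216 ± 9.53 to 36.9 ± 6.24 (log2 −2.53, SE 0.15, adjusted p = 0.0028). MPP4 (NM_033066), a scaffold protein of photoreceptors, fell from 109 ± 10.3 to 23.8 ± 1.76 (log2 −2.14, SE 0.14, adjusted p = 0.0039). These 4 genes and RBMX passed without each of the 6 libraries in turn.

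Other genes that fell were EVPL, the cornified envelope protein envoplakin (NM_001320747, 15.3 ± 1.15 against 146 ± 55.2, log2 −3.11), and KCNE1, a potassium channel subunit (NM_000219, 20.1 ± 7.63 against 153 ± 9.93, log2 −2.93). The tyrosine phosphatase PTPRE (NM_006504, 37.8 ± 6.05 against 159 ± 20.3, log2 −2.05), the butyrophilin BTN1A1 (NM_001732, 23.9 ± 2.85 against 102 ± 15.2, log2 −2.04) and LOC400710 (34.3 ± 6.57 against 163 ± 13.9, log2 −2.23) fell too. Their limma adjusted p values were 0.0075, 0.0081, 0.0057, 0.0057 and 0.0049, in that order. Without WT replicate 1 they were 0.072, 0.076, 0.058, 0.058 and 0.053, and KCNE1 was at 0.051 without WT replicate 3. LOC101929541 fell (log2 −2.06, adjusted p = 0.015), a call lost without NCV replicate 3 (0.051) or WT replicate 1, 2 or 3 (0.088, 0.079 and 0.080). PTCRA, the pre-T-cell receptor alpha chain (NM_138296), had from 0 to 5 reads in the NCV libraries and from 85 to 115 in WT.

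Genes higher in NCV were fewer. KRTAP19-1, a keratin-associated protein gene (NM_181607, chromosome 21, 31852018 to 31852697), rose from 416 ± 17.1 to 717 ± 40.0 (log2 0.78, SE 0.08, limma adjusted p = 0.0096), a call lost without NCV replicate 2 (0.056) or WT replicate 1 or 2 (0.067 and 0.052). INHBE, the inhibin beta E subunit (NM_031479), rose from 147 ± 14.8 to 253 ± 9.51 (log2 0.78, adjusted p = 0.028) and ADAMTS1, a secreted metalloprotease (NM_006988), from 12757 ± 403 to 15917 ± 247 (log2 0.32, adjusted p = 0.045). LINC00431 (log2 1.08, adjusted p = 0.037), LOC100422781 (0.62, 0.045) and the cilium gene CFAP52 (0.60, 0.047) rose as well. Each of these 5 missed the threshold without any 1 of the 6 libraries. In every gene named for this comparison, all 3 NCV libraries lay beyond all 3 WT libraries, which held for 14.9% of all genes, where chance gives 10%.

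In all, 7 genes rose and 159 fell of 19459 tested by limma-trend, while 1726 genes had an unadjusted p under 0.05. Genes past the threshold had a median mean level of 46.5, against 1466 over all genes, and 113 of the 166 had a mean below 100. edgeR called 9 genes up and 177 down, DESeq2 24 and 209, and 1 limma fit of all 15 libraries 65 and 352, and the authors' deposited table has 32 genes up and 232 down. The limma count was 67, 64 and 78 without NCV replicates 1, 2 and 3, and 10, 42 and 44 without WT replicates 1, 2 and 3, each time with 0 or 1 gene up. With a mean of at least 50 it was 50 (1 up, 49 down). With 1 surrogate factor of the libraries, chosen after the data were seen, 521 genes were higher and 808 lower.

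Among the gene lists, p53 targets tended down and immediate early genes up in NCV. Of 25 measured p53 targets, 22 were lower and 3 higher than in WT (median log2 −0.17, camera adjusted p = 7.6e-07, adjusted p = 0.088 with an estimated correlation). Over all genes 0 of them passed by limma-trend on these 6 libraries or by edgeR, 1 by DESeq2 and 2 in the limma fit of all 15 libraries (CDKN1A and TNFRSF10B, adjusted p = 0.015 and 0.016), 7 had an unadjusted p under 0.05, and 3 passed adjusted over the list alone. These were the cell cycle inhibitor CDKN1A (3277 ± 125 against 4487 ± 394, log2 −0.45, SE 0.08, adjusted p = 0.020), the death receptor TNFRSF10B (9418 ± 171 against 10933 ± 245, log2 −0.22, SE 0.05, 0.036) and the translesion polymerase POLH (4375 ± 183 against 5347 ± 362, log2 −0.29, SE 0.07, 0.036). All 23 immediate early genes had a positive value (median log2 0.22, camera adjusted p = 7.6e-07, adjusted p = 0.450 with an estimated correlation). Over all genes 0 passed by limma-trend on the 6 libraries or by edgeR, 2 by DESeq2 and 1 in the fit of 15 (EGR2, adjusted p = 0.025), 8 had an unadjusted p under 0.05, and 4 passed adjusted over the list alone. These were EGR1 (1959 ± 206 against 1339 ± 214, log2 0.56), EGR2 (105 ± 21.6 against 63.8 ± 5.78, log2 0.70), FOSB (809 ± 157 against 514 ± 77.3, log2 0.65) and ATF3 (4910 ± 58.1 against 4093 ± 67.1, log2 0.26), all transcription factors, with adjusted p from 0.024 for ATF3 to 0.046 for FOSB. In each of these 7 genes all 3 NCV libraries lay beyond all 3 WT libraries.

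Targets of ATF4 and the unfolded protein response were higher for 25 of 32 genes (median log2 0.10, camera adjusted p = 6.0e-04, adjusted p = 0.175 with an estimated correlation). Over all genes 0 passed by limma in either fit or by edgeR and 1 by DESeq2, 8 had an unadjusted p under 0.05 (7 up, 1 down), and 3 passed adjusted over the list alone, ATF3, the cystathionine lyase CTH (2399.6 ± 135 against 1825 ± 88.1, log2 0.39) and HERPUD1 (5274 ± 114 against 4571 ± 68.8, log2 0.21). In the hnRNPG family 4 of 5 genes were lower (median log2 −0.07, adjusted p = 0.0028, adjusted p = 0.248 with an estimated correlation). This list holds RBMX itself, the target of the siRNA and the gene on the plasmids, so its test says little beyond RBMX, which passed over all genes by each tool. RBMXL1 passed adjusted over the list alone, and over all genes by DESeq2 and in the limma fit of 15 libraries (adjusted p = 0.0091) but not by limma on the 6 or edgeR (3074 ± 122 against 4087 ± 290, log2 −0.41, SE 0.07, adjusted p = 0.0020 over the list alone). RBMXL1 is a near-identical retrocopy of RBMX, so reads can be shared between them and its fall is uncertain.

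Markers of other cell types passed too, at low levels. Blood and immune markers were lower for 6 of 7 genes (median log2 −0.38, adjusted p = 0.0080, adjusted p = 0.443 with an estimated correlation), with 0 past over all genes by limma, edgeR or DESeq2, 2 at an unadjusted p under 0.05, and 2 adjusted over the list alone, SPI1 (70.6 ± 8.90 against 99.3 ± 7.25, log2 −0.49) and CD74 (84.1 ± 3.58 against 127 ± 28.3, log2 −0.56), both at an adjusted p of 0.0495. Epithelial and liver markers were higher for 3 of 3 (median log2 0.18, adjusted p = 0.037, adjusted p = 0.369 with an estimated correlation), with 0 past over all genes by limma on the 6 libraries, edgeR or DESeq2 and 1 in the fit of 15, and 1 at an unadjusted p under 0.05. This was CDH1, the E-cadherin gene (adjusted p = 0.030 in the fit of 15), past adjusted over the list alone (773 ± 45.1 against 623 ± 15.0, log2 0.31, adjusted p = 0.011). Histone genes were higher for 14 of 16 (median log2 0.21, adjusted p = 0.037, adjusted p = 0.575 with an estimated correlation), with 0 past over all genes by the 3 tools or adjusted over the list alone, and 5 at an unadjusted p under 0.05 (4 up, 1 down).

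The lists closest to the study's questions did not pass in NCV. They were SR and Tra2 splicing factors (22 genes, median log2 −0.05, camera adjusted p = 0.180), hnRNP proteins (27, −0.03, 0.389), core spliceosome (34, −0.02, 0.148), m6A writers, erasers and readers (21, −0.01, 0.882), Pol II pausing and elongation (36, −0.02, 0.558) and sister chromatid cohesion (18, −0.01, 0.827). In these 6 lists 0 genes passed over all genes by limma, edgeR or DESeq2 or adjusted over the list alone, and 1 m6A gene and 1 cohesion gene had an unadjusted p under 0.05. The latter is ESCO1, a cohesin acetyltransferase (8389.5 ± 177 against 7063 ± 336, log2 0.25, adjusted p = 0.056 over the list alone). Also short of the threshold were the lists of DNA damage response (31 genes, median log2 −0.03, adjusted p = 0.691), S phase (26, −0.03, 0.284), G2 and mitosis (28, −0.01, 0.830), interferon response (25, 0.07, 0.234), heat shock (19, −0.07, 0.166), cholesterol synthesis (25, 0.00, 0.934), ribosomal proteins (72, 0.00, 0.934), oxidative phosphorylation (29, −0.01, 0.598), nonsense-mediated decay (20, −0.01, 0.648), nuclear long noncoding RNAs (6, −0.06, 0.598) and fibroblast and endothelial markers (7, 0.25, 0.101). In these 11 lists too 0 genes passed over all genes by limma, edgeR or DESeq2 or adjusted over the list alone. An unadjusted p under 0.05 was seen for 3 interferon genes, for 1 gene each of DNA damage response, heat shock, cholesterol synthesis, oxidative phosphorylation, nuclear long noncoding RNAs and fibroblast and endothelial markers, and for 0 in the other 4 lists.

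RRMmut was compared with WT to ask what the RNA recognition motif adds. RBMX was the 1 gene of 19500 past the threshold by limma-trend, 2.00-fold lower as given above, and 736 genes had an unadjusted p under 0.05. p53 targets were lower for 24 of 25 genes (median log2 −0.22, camera adjusted p = 1.6e-10, adjusted p = 0.049 with an estimated correlation). Over all genes 0 of them passed by limma-trend on these 6 libraries or by edgeR, 1 by DESeq2 and 1 in the limma fit of all 15 libraries (BTG2, adjusted p = 0.0012), 8 had an unadjusted p under 0.05, and 2 passed adjusted over the list alone. These were the antiproliferative gene BTG2 (2619 ± 54.8 against 3475 ± 71.0, log2 −0.41, SE 0.06, adjusted p = 0.0071, lower in 3 of 3 libraries) and CDKN1A (3337 ± 175 against 4439 ± 389, log2 −0.41, SE 0.09, adjusted p = 0.028, lower in 3 of 3). The hnRNPG family was lower for 5 of 5 (median log2 −0.08, adjusted p = 0.015, adjusted p = 0.371 with an estimated correlation), with RBMX past over all genes and adjusted over the list alone. RBMX is both the target of the siRNA and the gene on the plasmids, and the other members had an unadjusted p of 0.258 or more, so this list says nothing beyond RBMX. ATF4 targets were higher for 21 of 32 (median log2 0.05, adjusted p = 0.046, adjusted p = 0.672 with an estimated correlation), with 0 past over all genes by limma, edgeR or DESeq2 or adjusted over the list alone, and 5 at an unadjusted p under 0.05. EGR1, called higher in NCV within its list, was at 872 ± 140 in RRMmut against 1325 ± 214 (log2 −0.60, adjusted p = 0.141 over the list alone). The RBMX call was lost without RRMmut replicate 1 or 3 (0.105 and 0.193) or WT replicate 1, 2 or 3 (0.115, 0.079 and 0.070). edgeR called 1 gene, DESeq2 27, and the fit of all 15 libraries 33, and the authors' deposited table has 2 up and 26 down.

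**Figure D2:**
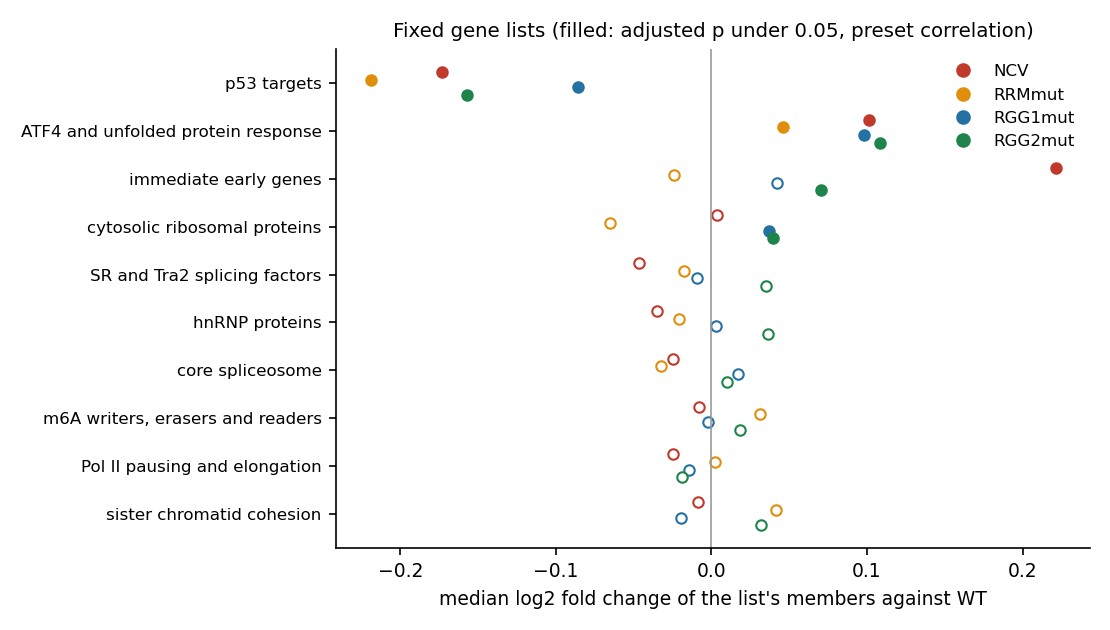
Median log2 fold change against WT of the members of 10 gene lists in NCV, RRMmut, RGG1mut and RGG2mut (filled circles, camera adjusted p under 0.05 with the preset correlation). p53 targets lie below 0 in all 4 comparisons, at −0.17, −0.22, −0.09 and −0.16, each set against the same WT libraries. With an estimated correlation they pass in RRMmut alone (adjusted p = 0.088, 0.049, 0.174 and 0.171).

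RGG1mut was compared with WT to ask what the first RGG region adds. No gene of 19533 passed by limma-trend or edgeR, with 481 at an unadjusted p under 0.05. DESeq2 called 6, the fit of all 15 libraries 2, and the authors' deposited table has 6 genes down, with RBMX among them, and 0 up (log2 of RBMX −0.40, the authors' adjusted p = 0.0076). p53 targets were lower for 22 of 25 genes (median log2 −0.09, camera adjusted p = 1.4e-04, adjusted p = 0.174 with an estimated correlation) and ATF4 targets higher for 25 of 32 (0.10, 3.8e-04, adjusted p = 0.560 with an estimated correlation). In these lists 0 genes passed over all genes by the 3 tools or adjusted over the list alone, with 2 p53 targets and 1 ATF4 target at an unadjusted p under 0.05. BTG2 had the lowest p of the p53 targets (3038 ± 51.3 against 3539.5 ± 75.8, log2 −0.22, adjusted p = 0.098 over the list alone) and CTH of the ATF4 targets (2103 ± 141 against 1839 ± 89.5, log2 0.19, 0.364). Ribosomal protein genes were higher for 69 of 72, by little (median log2 0.04, adjusted p = 0.019, adjusted p = 0.637 with an estimated correlation), with 0 past by the 3 tools or adjusted over the list alone and 0 at an unadjusted p under 0.05. RBMX passed adjusted over the hnRNPG family alone (adjusted p = 6.7e-04), whose own test gave 0.090. Groups did not overlap for 6.98% of genes, against 8.90% in RRMmut and 8.50% in RGG2mut, where chance gives 10%.

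RGG2mut was compared with WT to ask the same of the second RGG region. No gene of 19487 passed by limma-trend or edgeR or in the fit of all 15 libraries, with 660 at an unadjusted p under 0.05, while DESeq2 called 3 and the authors' deposited table has 3 genes down and 0 up. ATF4 targets were higher for 23 of 32 genes (median log2 0.11, camera adjusted p = 7.5e-05, adjusted p = 0.745 with an estimated correlation). Among them were PSAT1 of serine synthesis (22196 ± 1835 against 18323 ± 791, log2 0.27) and CTH (2463 ± 379 against 1835 ± 83.7, log2 0.41), both at an adjusted p of 0.071 over the list alone and higher in 3 of 3 libraries. p53 targets were lower for 24 of 25 (median log2 −0.16, adjusted p = 7.8e-05, adjusted p = 0.171 with an estimated correlation), with BTG2 at 3097 ± 91.0 against 3532 ± 73.2 (log2 −0.19, 0.351 over the list alone). Immediate early genes were higher for 14 of 23 (0.07, adjusted p = 0.0052, adjusted p = 0.745 with an estimated correlation). Ribosomal protein genes were higher for 46 of 72 (median log2 0.04 but mean −0.01, adjusted p = 0.034, adjusted p = 0.745 with an estimated correlation). In these 4 lists 0 genes passed over all genes by the 3 tools or adjusted over the list alone, with 7, 2, 7 and 5 at an unadjusted p under 0.05. RBMX passed adjusted over the hnRNPG family alone (adjusted p = 0.0070), whose own test gave 0.26. Differences between the mutants in these lists were not tested.

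All other lists missed the threshold in each mutant. For the study's own topics the camera adjusted p in RRMmut, RGG1mut and RGG2mut was 0.504, 0.889 and 0.381 for SR and Tra2 splicing factors and 0.435, 0.761 and 0.313 for hnRNP proteins. It was 0.729, 0.619 and 0.544 for the core spliceosome, 0.168, 0.761 and 0.498 for m6A writers, erasers and readers, 0.980, 0.758 and 0.544 for Pol II pausing and elongation, and 0.165, 0.619 and 0.381 for sister chromatid cohesion. In these 6 lists 0 genes passed over all genes by limma, edgeR or DESeq2 or adjusted over the list alone, and an unadjusted p under 0.05 was seen for 1 cohesion gene in RRMmut, 2 m6A genes in RGG1mut and 0 others.

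The mutants were next compared with NCV, which asked whether supplying mutated hnRNPG changed the transcripts. Here 171 genes were higher and 19 lower in RRMmut, 187 and 43 in RGG1mut, and 175 and 32 in RGG2mut (limma, 1 fit of 15 libraries). With the 6 libraries of the 2 groups alone these were 29 and 1, 26 and 1, and 22 and 3. FAM83C was at 116 ± 23.0 in RRMmut against 12.4 ± 2.42 in NCV (log2 3.11, SE 0.20, adjusted p = 5.1e-06), FAM71F1 differed by log2 3.07, and LEXM was at 193 ± 22.3 against 33.8 ± 2.92 (log2 2.47). In RGG1mut, EVPL was at 141 ± 44.0 against 15.5 ± 1.17 (log2 3.05, adjusted p = 3.0e-04). The axonemal dynein DNAH10 was at 357 ± 7.97 in RGG1mut and 428 ± 22.8 in RGG2mut against 145 ± 3.74 in NCV (log2 1.29 and 1.55, adjusted p = 7.7e-06 and 8.5e-07). The sialyltransferase ST6GALNAC2 rose in both RGG mutants (log2 1.47 and 1.36), and the potassium channel subunit KCNE1 in all 3 mutants (log2 2.12, 1.97 and 2.42). CATSPERD, a sperm calcium channel subunit, rose in all 3 as well (log2 1.89, 1.72 and 1.59), as did RBMX (log2 3.19, 3.80 and 3.80).

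Fewer genes were lower in the mutants than in NCV. EGR1, an immediate early transcription factor, was at 890 ± 142 in RRMmut and 927 ± 122 in RGG1mut against 1981 ± 207 in NCV (log2 −1.16 and −1.10, SE 0.16 for both, adjusted p = 0.0022 and 0.0035). KRTAP19-1 was at 444 in RGG2mut against 725 in NCV (log2 −0.71, adjusted p = 8.4e-04), and CFAP52 also fell in RGG2mut (log2 −0.57, adjusted p = 0.0044). All genes named for these comparisons had groups of 3 libraries that did not overlap, and all kept their call without each of the 6 libraries. With the 6 libraries of the 2 groups alone, KCNE1 missed the threshold in RRMmut, RGG1mut and RGG2mut (limma adjusted p = 0.072, 0.108 and 0.053), as did KRTAP19-1 and CFAP52 in RGG2mut (0.063 and 0.144). Without any 1 of these 6 libraries the lower genes numbered from 5 to 11 in RRMmut, from 9 to 18 in RGG1mut and from 6 to 20 in RGG2mut. Without RRMmut replicate 2 the RRMmut count of 190 was 113. The RGG1mut count of 230 was 131, 145 and 137 without NCV replicates 1, 2 and 3, and 126, 113 and 147 without RGG1mut replicates 1, 2 and 3. The RGG2mut count of 207 was 135 and 124 without NCV replicates 1 and 2, and 135, 123 and 133 without RGG2mut replicates 1, 2 and 3.

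Of the 158 genes other than RBMX that fell in NCV against WT, 154 were tested against the mutants. Of these, 99 passed as higher in RRMmut than in NCV, 120 in RGG1mut and 114 in RGG2mut, while 1.40, 1.53 and 1.43 would be shared if the calls were independent. Median differences from NCV were log2 1.11, 1.21 and 1.17, with a positive value for 152, 154 and 154 genes. Both comparisons used the same NCV libraries, which favours such a result without any effect. In 100 simulated sets of unchanged groups, the 158 genes of lowest p that were lower in 1 group than in another were higher in a separate group for a median of 88.9%, by a median log2 of 0.15, and 0 of them passed in the median set but 158 in the highest. Against WT, in the fit of 15 libraries, 23 of these genes were lower in RRMmut, 2 in RGG1mut and 0 in RGG2mut by limma, with median log2 values of −0.52, −0.44 and −0.42, against −1.75 in NCV. The 4 comparisons with WT share its 3 libraries, and across 19235 genes their fold changes correlated at r from 0.36 (NCV and RGG2mut) to 0.66 (RRMmut and RGG2mut). Simulated libraries with no effect but the shared WT gave r = 0.49 and a covariance of 0.023, against observed covariances from 0.012 to 0.028. Genes are not independent replicates in these correlations.

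**Figure D3:**
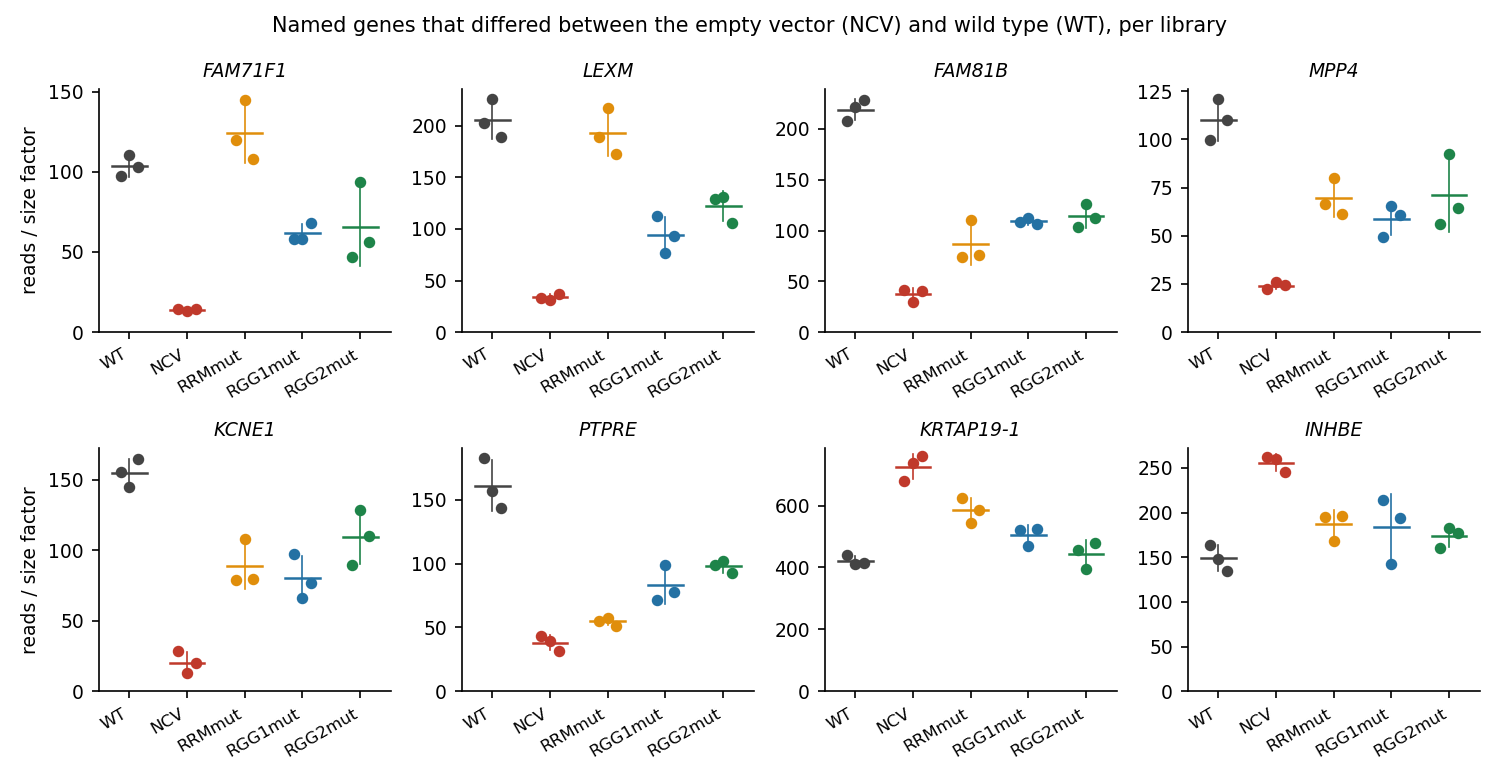
Normalised reads of 8 named genes in each library of the 5 groups (linear axis from 0), with group means and SD. FAM71F1, LEXM, FAM81B, MPP4, KCNE1 and PTPRE are lower in NCV than in WT, and KRTAP19-1 and INHBE higher.

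Exon levels and exon usage were compared to ask which exons depend on hnRNPG, a splicing factor. In NCV, 11 of 163720 exons fell (limma), 9 in RBMX and 2 in FAM120C, and edgeR called 12. The 2 FAM120C exons are overlapping forms of its last exon (chromosome X, 54094757 to 54099720 in the longer), at 72.8 ± 9.22 against 328 ± 12 in WT (log2 −2.16, SE 0.12, limma adjusted p = 0.010, edgeR 0.0096). The call was lost without NCV replicate 1 or 2 (0.16 and 0.095) or WT replicate 1, 2 or 3 (0.242, 0.071 and 0.096). Of the 15 measured FAM120C exons, the 12 farther along the gene were lower in NCV, each with an unadjusted p under 0.05, while the exon at 54200222 to 54200579 had 416 ± 44.1 against 372 ± 12.6. The last exon was at 175 ± 16.4 in RRMmut (log2 −0.89), 228 ± 6.31 in RGG1mut (−0.54) and 264 ± 6.68 in RGG2mut (−0.32), and these did not pass (limma adjusted p from 0.973 to 1). FAM120C was chosen after its values were seen. The authors' deposited table has 2 exons up and 25 down in NCV, 0 and 11 in RRMmut, 0 and 4 in RGG1mut and 0 and 0 in RGG2mut. 

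Usage sets an exon against the rest of its gene. The last listed exon of JPX, a long noncoding RNA gene (chromosome X, 73289004 to 73290217), had 48.1 ± 9.21 against 123 ± 6.06 in WT (usage log2 −1.43, SE 0.12, limma diffSplice adjusted p = 5.9e-06). The last listed exon of ZNF346 (chromosome 5, 176506383 to 176508190) had 365 ± 24.5 against 194 ± 6.70 (usage log2 0.95, SE 0.13, adjusted p = 2.0e-05). An exon of NFX1 (chromosome 9, 33347661 to 33348721) had 1423 ± 187 against 1033 ± 60.1 (usage log2 0.74, adjusted p = 4.2e-05). Lower usage was called at the last listed exons of TMEM161B-AS1 (usage log2 −1.28) and ZNF738 (−1.20) and at the first of EIF5, a translation initiation factor gene (−1.01). These 6 exons passed without each of the 6 libraries. FAM120C (usage log2 1.89) missed the threshold without NCV replicate 1 or 2 or WT replicate 1 or 3 (adjusted p = 0.151, 0.103, 0.16 and 0.141), and ANXA4 (0.75) without NCV replicate 1 or 2 or WT replicate 1 or 2 (0.831, 0.068, 0.363 and 0.192). TMEM161B-AS1 and JPX overlap or neighbour genes of the other strand, and the strand setting of the counting is not given, so their reads are uncertain.

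In all, limma diffSplice called 137 of 160903 exons in NCV, 56 with higher and 81 with lower usage, in 101 genes, and 11 of them lie in RBMX. The RBMX calls, here and in the mutants, can come from unequal plasmid reads over its inner exons, so they are uncertain as a measure of splicing. With the surrogate factor as a covariate all 137 still passed, as did 33 of 39 in RRMmut, 31 of 31 in RGG1mut and 61 of 88 in RGG2mut. Most of the NCV calls outside RBMX did not pass in versions of the test that measure the spread in another way. With precision weights 55 exons passed, 27 of them among the 126 outside RBMX, and with a variance for each exon 12 passed, 1 of them outside RBMX (FAM120C, chromosome X, 54200222 to 54200579, usage log2 1.79, adjusted p = 0.0027). With such a variance and the surrogate factor 95 passed, 23 of them among the 126. edgeR called 6. In simulated data limma diffSplice made 328 false calls of 454, so calls outside RBMX are not established. There the variance for each exon found 2% of 2-fold and 60% of 4-fold changes, against 44 and 84% with limma diffSplice, and edgeR 28 and 80%, so a call missed by these is not shown to be false. The count of 137 was 73 (22 higher, 51 lower) and 83 (23 and 60) without NCV replicates 1 and 2, 72 (27 and 45) without WT replicate 1, and 186 (131 and 55) without WT replicate 2, which turned the balance over.

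In RRMmut, the RBMX exon at 135951353 to 135952576 had higher usage (log2 1.00), and the RBMX exon at 135961478 to 135961612 fell more than the rest of the gene (23865 ± 1359 against 60855 ± 4741, usage log2 −0.66). That exon's usage missed the threshold without RRMmut replicate 3 (0.051) or WT replicate 2 (0.074). The JPX exon was at 81.0 ± 4.90 against 122 ± 6.70 (usage log2 −0.71, limma adjusted p = 0.027), a call lost without RRMmut replicate 1 or 3 (0.073 and 0.305) or WT replicate 1 or 2 (0.323 and 0.333). BAZ1A, a chromatin remodelling gene (usage log2 −0.84), missed it without RRMmut replicate 2 or 3 or WT replicate 2 (1, 0.576 and 1). The RNA helicase gene DDX5 (−0.83) missed it without RRMmut replicate 2 or 3 or WT replicate 1 or 2 (0.830, 0.157, 0.851 and 0.074). The 39 calls among 160124 exons, 4 of them in RBMX, became 4 with precision weights, 0 with a variance for each exon (2588 at an unadjusted p under 0.05) and 3 with edgeR. Usage was higher in 14 and lower in 25. The calls became 130 (12 higher, 118 lower), 58 (17 and 41) and 17 (7 and 10) without RRMmut replicates 1, 2 and 3, and 20 (6 and 14), 9 (9 and 0) and 497 (52 and 445) without WT replicates 1, 2 and 3. Of the 24 exons with lower usage outside RBMX, 12 were the first listed exon of their gene.

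In RGG1mut, the RBMX exon at 135954427 to 135954504 had higher usage (log2 0.52) and the RBMX exon at 135960074 to 135960245 lower (59736 ± 1269 against 96259 ± 4643, usage log2 −0.43). The first was lost without RGG1mut replicate 2 (limma adjusted p = 0.066), and the second without RGG1mut replicate 1, 2 or 3 (0.254, 0.426 and 0.082) or WT replicate 1 (0.105). The JPX exon was at 79.4 ± 3.09 against 125 ± 6.04 (usage log2 −0.67), a call lost without RGG1mut replicate 1, 2 or 3 (0.082, 0.271 and 0.094) or WT replicate 1 or 2 (0.214 and 0.075). Here 31 of 160980 exons were called, 4 of them in RBMX, 4 with precision weights, 0 with a variance for each exon and 0 by edgeR (1838 and 58 at an unadjusted p under 0.05). With 15 higher and 16 lower, the count was 21 (9 and 12), 7 (3 and 4) and 63 (40 and 23) without RGG1mut replicates 1, 2 and 3, and 21 (10 and 11), 84 (66 and 18) and 68 (30 and 38) without WT replicates 1, 2 and 3.

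In RGG2mut, 43 of the 73 exons with lower usage were the first listed exon of their gene. Among them were USP24, a deubiquitinase gene (55.3 ± 18.0 against 125 ± 63.0, usage log2 −0.98), the chromatin remodelling gene CHD7 (49.1 ± 14.4 against 86.9 ± 20.2, −0.77), HMGXB3 (−0.76), the DNA glycosylase gene NEIL3 (−0.74) and GIT2 (−0.73). Higher usage was called in PURG (0.95), in CNOT9 (90.5 ± 12.3 against 52.3 ± 0.82, usage log2 0.77), in RBMX (0.55) and in SARS (0.52). Of these 9 exons CNOT9 alone passed without each of the 6 libraries, while the other 8 missed the threshold without RGG2mut replicate 3 (adjusted p from 0.079 for PURG to 1) and without WT replicate 2 (from 0.205 for SARS to 1). All but USP24 missed it without RGG2mut replicate 2 too (from 0.072 for SARS to 1), and all but USP24 and HMGXB3 without WT replicate 1 (from 0.084 for PURG to 0.818). Of the 88 called exons among 160198, 0 were called with precision weights, with a variance for each exon or by edgeR (3767, 5173 and 753 exons at an unadjusted p under 0.05). With 15 higher and 73 lower, the count was 1085 (49 and 1036), 48 (11 and 37) and 18 (4 and 14) without RGG2mut replicates 1, 2 and 3, and 30 (4 and 26), 27 (14 and 13) and 911 (53 and 858) without WT replicates 1, 2 and 3. No exon level passed in RRMmut, RGG1mut or RGG2mut by limma or edgeR (2215, 1638 and 3716 exons had an unadjusted p under 0.05).

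A MED23 exon, of a Mediator subunit gene (chromosome 6, 131895106 to 131895435), had higher usage in all 4 comparisons (log2 1.08, 1.10, 0.87 and 0.78 in NCV, RRMmut, RGG1mut and RGG2mut), on levels of 32.7 in NCV against 16.2 in WT. It was chosen after its values were seen. Pairs of comparisons shared 7 called exons (NCV and RRMmut), 11 (NCV and RGG1mut), 5 (NCV and RGG2mut), 5 (RRMmut and RGG1mut), 4 (RRMmut and RGG2mut) and 4 (RGG1mut and RGG2mut), each exon in the same direction. Independent calls would share 0.015, 0.011, 0.038, 0.0031, 0.012 and 0.0079. The same WT libraries enter all 4 comparisons, which alone makes calls coincide.

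PAR-CLIP asked where hnRNPG touches nascent RNA. Its 3186377 sites (median 36 nt) were denser on listed exons than elsewhere in genes, and denser in splicing factor and ribosomal protein genes than in the median gene. Of all sites, 65.4% lay on the strand of a listed gene, 4.89% only opposite one and 29.7% in none. Sites on the listed exons of all 17097 symbols equalled 29.6% of the sense sites, and the length of these exons 7.33% of the gene length. Sense sites and gene length were taken over the 15888 kept genes alone, so both shares are approximate. Listed exons had 10.7 sites per kb, against 2.41 in other gene sequence within 250 nt of an exon, which the same mismatch sets too high, and 2.02 farther away. Sites were found in 13298 of 15888 genes (83.7%), with a median of 2.13 per kb over all of them. RBMX itself had 253 sites, 21.8 per kb, and 0 on the opposite strand. By list, the median density was 26.1 per kb in nuclear-retained long noncoding RNAs (NEAT1, the paraspeckle RNA, had 653 sites), 16.7 in the hnRNPG family, 15.8 in hnRNP proteins (HNRNPA2B1, 393 sites, 36.2 per kb) and 15.8 in cytosolic ribosomal proteins (RPS2, 90 sites, 32.5 per kb). It was 14.4 in SR and Tra2 splicing factors (SRSF1, 210 sites, 32.7 per kb), 7.22 in m6A writers, erasers and readers, 5.93 in Pol II pausing factors and 2.66 in p53 targets. Few sites lay in interferon response genes (12 of 23 with a site), immediate early genes (13 of 21), or markers of blood (3 of 6) and fibroblasts (0 of 6), and densities were not adjusted for how strongly a gene is transcribed.

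The 10 genes with the most sites spanned from 223 to 1504 kb. PRH1-PRR4 had 3730 (hg19 chromosome 12, 10999644 to 11324224) and the overlapping PRH1 3536, which share sites. GPHN, the synapse scaffold gephyrin, had 3636, MIR924HG 3517, AUTS2 3511, FHIT 3428, SLIT2, an axon guidance gene, 3260, DOCK3 3105, the chromatin regulator ANKRD11 3053 (chromosome 16, 89334029 to 89556969) and FAF1 2947.

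Exons called for usage in NCV lay near these sites more often than matched exons. Of 137 called exons, 104 (75.9%) had a site within 250 nt on either strand. In random exons matched on expression and length the share was 55.2% (central range 47.4 to 62.8%, one-sided permutation p = 1e-04, the smallest that 10000 sets can give). Over all tested exons the share was 75.3%. Without the RBMX exons it was 93 of 126 (73.8% against 51.6%, permutation p = 1e-04). The permutation takes exons of the same gene as independent. In RGG1mut it was 25 of 31 exons (80.6% against 47.7%, permutation p = 4.0e-04), in RRMmut 22 of 39 (56.4% against 47.5%, p = 0.156) and in RGG2mut 39 of 88 (44.3% against 46.3%, p = 0.685). With calls by precision weights in NCV the share was 89.1% of 55 exons against 81.1% (permutation p = 0.067). Counting sites on the gene's strand alone gave 73.7% of 137 exons in NCV against 49.3% (permutation p = 1e-04). In RGG2mut the difference from random exons depended on how sites were counted. It was 15.2 percentage points for a site within 1000 nt (permutation p = 0.0018), −11.1 for a site on the exon itself (22 of 88 exons, random range 27.3 to 45.5%) and −11.4 with matching also on gene expression (44.3%, random range 45.5 to 65.9%). That matching gave 10.6 points in NCV (permutation p = 0.0017), 20.8 in RGG1mut (0.0067) and −3.15 in RRMmut (0.731).

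**Figure D4:**
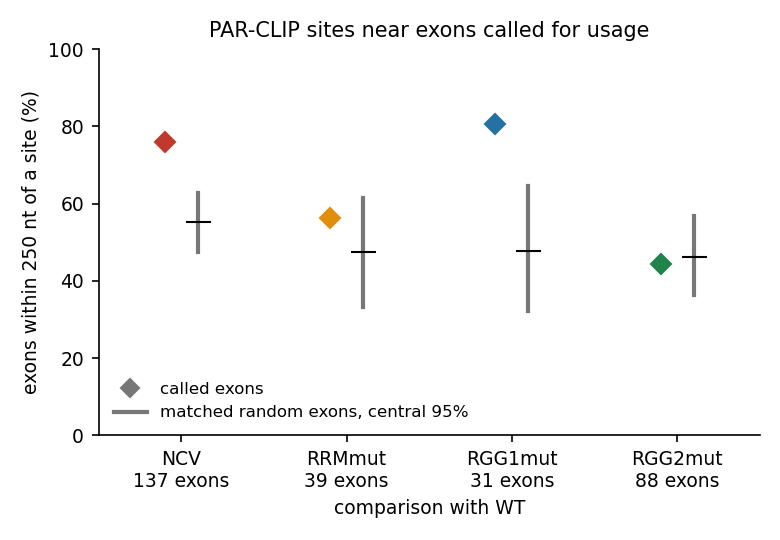
Percent of exons called for usage with a PAR-CLIP site within 250 nt on either strand (diamonds), for the 4 comparisons with WT. Bars show the mean and central 95% of matched random sets. NCV (75.9%) and RGG1mut (80.6%) lie above their random sets.

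ChIP-seq asked how Pol II and its phosphorylated forms change when hnRNPG is lowered by siRNA for 48 h. Peaks were fewer with sihnG3 than with the control siRNA for each antibody. Pol II had 6500 peaks in siC, 2467 in sihnG3 and 5489 in sihnG4, covering 3.38, 1.17 and 2.69 Mb. S5P, the form enriched near gene starts, had 6330, 3292 and 5962 peaks, covering 3.98, 1.93 and 3.41 Mb. S2P, the form of elongating polymerase, had 7608, 5549 and 8215 peaks. The total length of the S2P peaks in sihnG3 and sihnG4 was 71.5 and 94.6% of that in siC (12985439 bp). Of the sequence within siC S2P peaks, sihnG3 and sihnG4 peaks overlapped 51.4 and 60.2%. Each list comes from 1 library, so differences between siRNAs have no replicate check. A list's length also depends on depth, enrichment and the threshold, which the labels do not state.

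Most Pol II peaks lay within 1000 bp of a gene start (79.3% in siC, 64.2% in sihnG3, 78.6% in sihnG4), as did most S5P peaks (73.8, 67.9 and 75.2%). Of 15888 gene starts, 6077 had a Pol II peak in siC, 1885 in sihnG3 and 5119 in sihnG4. For S5P they were 5559, 2704 and 5347, and for S2P 3354, 1130 and 4589. Of the gene starts with a siC peak, 1852 (Pol II), 2573 (S5P) and 1071 (S2P) had one in sihnG3, and 4569, 4482 and 2876 in sihnG4. Cytosolic ribosomal protein genes had a Pol II peak at 72 of 72 starts in siC, 49 in sihnG3 and 68 in sihnG4. Core spliceosome genes had one at 28 of 35 in siC, 7 in sihnG3 and 23 in sihnG4, hnRNP genes at 26 of 29, 10 and 26, and Pol II pausing and elongation genes at 26 of 36, 9 and 25. Cholesterol synthesis genes had one at 14 of 25, 1 and 11. Over all gene starts the sihnG3 number was 31.0% of that in siC, so a lower count in sihnG3 is not particular to these lists. Some lists kept more, among them nonsense-mediated decay (16 of 20, 13 and 16), heat shock (17 of 19, 12 and 15) and SR and Tra2 splicing factors (19 of 22, 12 and 17). S2P peaks at starts of sister chromatid cohesion genes were seen at 6 of 18 in siC, 0 in sihnG3 and 4 in sihnG4, and of G2 and mitosis genes at 15 of 28, 1 and 19.

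sihnG3 peaks overlapped 31.2% of the siC Pol II peaks (exact 95% interval 30.1 to 32.4), 45.0% of the S5P (43.7 to 46.2) and 45.2% of the S2P peaks (44.1 to 46.4). sihnG4 peaks overlapped 71.5% (70.4 to 72.6), 73.4% (72.3 to 74.5) and 64.3% (63.2 to 65.4). A shorter list lowers such a share, and the sihnG3 Pol II list had 2467 peaks against 6500 in siC. Of the 1885 gene starts with a Pol II peak in sihnG3, 1852 also had one in siC. Outside 1 locus on the X chromosome, which held longer S2P and S5P peaks and is not shown, the longest siC S2P peaks were at NFS1, ROMO1 and RBM39 (chromosome 20, 34287117 to 34324638, 37.5 kb), HNRNPC (chromosome 14, 21702461 to 21737744, 35.3 kb) and COX20 and HNRNPU (chromosome 1, 244997658 to 245028112, 30.5 kb). Peaks of sihnG3 and sihnG4 covered 94.5 and 96.9% of the first and 99.8 and 100% of the HNRNPC peak. For S5P, the HNRNPU locus (chromosome 1, 244997305 to 245018491) and NFE2L3 with HNRNPA2B1 (chromosome 7, 26221944 to 26233143) were among the 3 longest outside that locus. Peaks of sihnG3 and sihnG4 covered less of these, 83.0 and 77.4% of the HNRNPU peak and 78.7 and 93.5% of the HNRNPA2B1 peak. The other long S5P peak, at chromosome 16, 46385862 to 46409028, and the 3 longest Pol II peaks (chromosome 16, 46385867 to 46409073 and 46420236 to 46429215, and chromosome 10, 42364614 to 42376493) lay in no listed gene. The fold over background of these Pol II peaks was 1.77, 2.04 and 2.49, against a median of 3.43 over siC Pol II peaks. That of the S5P peak was 1.71 against 3.39. They are uncertain as sites of Pol II, and artifacts were not checked for.

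**Figure D5:**
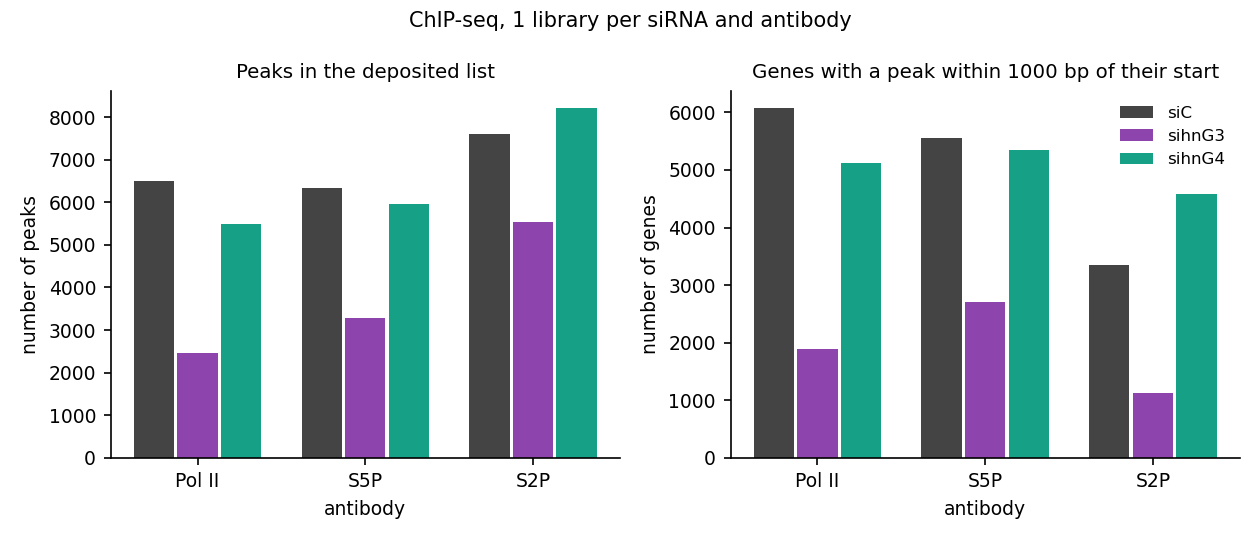
Number of peaks in the deposited lists and number of genes with a peak within 1000 bp of their start, for Pol II, S5P and S2P after siC, sihnG3 or sihnG4 (bars, 1 library each). sihnG3 has the lowest bar for each antibody, while sihnG4 exceeds siC for S2P, with 8215 peaks against 7608.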

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

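The test of genes with fewer than 4 listed exons and the test of first exon coverage were chosen after the results were seen, as were the library factor, the matching on gene expression and a stricter reading of the 3′ coverage test.

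In S2P ChIP-seq, 3 measures lay on opposite sides of the control siRNA with the 2 hnRNPG siRNAs, while the covered length was lower with both (71.5% of siC with sihnG3, 94.6% with sihnG4). S2P peaks numbered 5549 with sihnG3 and 8215 with sihnG4, against 7608 in siC. Their median width was 878 bp with sihnG3 and 773 bp with sihnG4, against 869 bp. Genes with an S2P peak at their start numbered 1130 with sihnG3 and 4589 with sihnG4, against 3354. With 1 library each these differences were not tested.

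Genes that fell in NCV were mostly of low level and mostly higher in the mutants than in NCV (152, 154 and 154 of 154 genes in RRMmut, RGG1mut and RGG2mut), which their selection on the NCV libraries favours. The tables argue against plasmid reads counted in other genes, because in the 16 genes with 4 or more listed exons the drop covered a median share of 1 of the remaining exons. In genes with fewer exons the return in RRMmut was at least 0.754 of that in the RGG mutants (lowest library median over 141 genes), above the highest RBMX value of 0.661. They also argue against a lower background in NCV, since all 3967 genes with a mean from 10 to 100 had a median log2 of 0.0077. What stays open is that these genes may follow the amount of hnRNPG message, as their levels in RRMmut, with the least RBMX of the mutants, lay at a median log2 of −0.14 from the RGG mutants (99 of 157 genes lower, exact one-sided p = 0.012 over 84 splits), which is also what a specific role of the RNA recognition motif could give.

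Libraries of the same group differed along 1 shared factor, and 43 first listed exons had lower usage in RGG2mut, as had 12 in RRMmut (8 still past the threshold with the factor), for which no other test was made. In every group the factor was negative in replicate 1 and positive in replicate 3, with replicate 2 on either side, so it partly followed the replicate number. The factor may reflect coverage of first exons, with which it correlated within groups over 15 libraries at r = −0.91 (Spearman −0.91, permutation p = 0.0013 and 0.0011, adjusted over 3 measures 0.0038 and 0.0034, r = −0.90 without 2 libraries), although both come from the same reads. Sequencing depth (r = 0.57, Spearman 0.61, adjusted permutation p = 0.105 and 0.063, r = 0.58 without 2) and 3′ coverage (r = 0.25, Spearman 0.35, 0.403 and 0.251, r = 0.39 without 2) stay open, the latter because its r, under the bound of 0.3 set for excluding it, rose above it without 2 libraries. For the first exons in RGG2mut a lower coverage in that group cannot be told apart from changed usage, since 2 of its 3 libraries lay below all WT libraries. The factor as a covariate left 62.8% of these exons past the threshold (27 of 43), between the bounds set for and against it, and no biological explanation was tested.

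Exons called for usage in NCV had PAR-CLIP sites nearby more often than matched exons. Matching on expression of the whole gene left an excess of 10.6 percentage points (permutation p = 0.0017). This count held the 11 RBMX exons and took exons of the same gene as independent, so it cannot exclude gene expression as the sole reason. False calls of the usage test stay open, as in simulated data with a spread for each exon 52.4% of 328 false calls lay near a site, against 59.9% of matched exons, but with a spread set by the mean alone it was 63.4% of 41 against 48.2% (permutation p = 0.028). Matched also on gene expression, the false calls gave permutation p = 1 and 0.353, but simulated settings exclude nothing. Direct binding by hnRNPG is consistent with the excess and was not tested further.

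With 3 libraries against 3 there are 10 splits, which cannot give a share under 0.05. In NCV against WT, 2 splits gave as many genes as the real 166 (highest other 1080), 2 as many exons as 11 (17511), 5 as many usage calls as 137 (9656) and 1 as many lists as 7 (6), of which the hnRNPG family holds RBMX itself, as it does in RRMmut. In RRMmut these were 2 splits for 1 gene (3298), 10 for 0 exons (17342), 7 for 39 usage calls (6126) and 10 for 3 lists (8). In RGG1mut they were 10 for 0 genes (2478), 10 for 0 exons (20541), 8 for 31 usage calls (9858) and 6 for 3 lists (6). In RGG2mut they were 10 for 0 genes (8467), 10 for 0 exons (49815), 5 for 88 usage calls (15800) and 5 for 4 lists (6). Splits that call many times the real count point to a structure of the samples. Against NCV, 1 split, the real one, gave as many genes in RRMmut (190), RGG1mut (230) and RGG2mut (207), with 0 genes in the highest other split. These splits were made within the fit of all 15 libraries, whose spread rests on every group, while those against WT used 6 libraries. The 2 kinds of split are not alike, so the count of 0 does not show that such a structure is absent. With the 6 libraries alone, where no splits were run, the real counts were 30, 27 and 25.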

How the results depend on the processing

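Settings with a surrogate factor, precision weights or a variance for each exon, and PAR-CLIP counts by strand, gene expression or weighted calls, were chosen after the data were seen. Where counts moved the cause was not tested, unless the setting itself shows it. Counts are in the order NCV, RRMmut, RGG1mut and RGG2mut unless said otherwise.

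Genes changed against WT (166, 1, 0 and 0) moved to 50 in NCV with a mean of at least 50, which tests fewer genes. They moved to 27, 6 and 3 with DESeq2 in the 3 mutants, to 417 (65 up, 352 down), 33 and 2 in NCV, RRMmut and RGG1mut with all 15 libraries in one fit, and to 1329 (521 up, 808 down), 177, 9 and 13 with the surrogate factor. A replicate block gave 830 (309 up, 521 down), 0, 0 and 0 genes, 49 exons in NCV, and 381, 23, 51 and 54 usage calls. With it the core spliceosome list passed in NCV as lower (camera adjusted p = 0.033, preset correlation, 0.855 with an estimated correlation). Lists that lost their call were epithelial and liver markers in NCV (0.062), ATF4 targets in RRMmut (0.084) and ribosomal proteins in RGG2mut (0.065). Libraries of the same number paired across groups only in part (in NCV 2, RRMmut 0, RGG1mut 2 and RGG2mut 1 of 3 pairs correlated above 0.1 with WT). In every group the surrogate factor was negative in replicate 1 and positive in replicate 3, while replicate 2 varied. An effect of the replicate number is therefore not excluded, and no paired result is given elsewhere. Leaving out a library gave from 10 to 78 genes in NCV, from 0 to 1 in RRMmut, and 0 in RGG1mut and RGG2mut.

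Genes different from NCV in RRMmut, RGG1mut and RGG2mut (190, 230 and 207) moved to 80, 104 and 98 with a mean of at least 50, to 30, 27 and 25 with the 6 libraries of the groups alone, where the spread rests on fewer libraries, and to 429, 870 and 721 with the surrogate factor. With the factor 317, 611 and 437 were higher and 112, 259 and 284 lower, a larger share lower than in the main fit. Leaving out a library gave from 113 to 147, from 113 to 147 and from 123 to 149.

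Exons changed (11, 0, 0 and 0) moved to 504 (196 up, 308 down), 8, 8 and 93 (29 up, 64 down) with the surrogate factor, and leaving out a library gave from 9 to 11 in NCV and 0 in the mutants. Usage calls (137, 39, 31 and 88) moved to 53, 7, 5 and 12 with a mean of at least 50, 83, 16, 14 and 44 with pseudocount 5, 555, 86, 220 and 257 with the surrogate factor, 55, 4, 4 and 0 with precision weights, 12, 0, 0 and 0 with a variance for each exon, 6, 3, 0 and 0 with edgeR, and 0, 3 and 0 in the mutants with a variance for each exon and the factor, which gave 95 in NCV. Leaving out a library gave from 72 to 186, from 9 to 497, from 7 to 84 and from 18 to 1085.

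Lists past the threshold (7, 3, 3 and 4, with the hnRNPG family, which holds RBMX, among them in NCV and RRMmut) became 0, 1, 0 and 0 with an estimated correlation. The PAR-CLIP excess in NCV (20.7 points) was weaker, 8.04 points, with weighted calls. It changed sign to −3.15 in RRMmut with matching on gene expression, and in RGG2mut to 15.2 within 1000 nt and 0.36 on the gene's strand. In 17 other settings the PAR-CLIP excess kept its direction and its side of the threshold, but its size moved, as to 10.6 in NCV and 20.8 in RGG1mut with matching on gene expression, and to 1.45 in RRMmut and −11.1 in RGG2mut for a site on the exon.

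Shares of siC peaks overlapped with sihnG3 and sihnG4 moved to 21.8 and 64.6% (Pol II), 30.5 and 50.8% (S2P) and 34.4 and 66.1% (S5P) when at least 50% of the siC peak had to be covered, a stricter demand. In the upper part of each list by score they moved to 62.3% (Pol II, sihnG4), 66.3% (S2P, sihnG4), and 41.3 and 66.0% (S5P). Of the other settings for counts and shares, 70 stayed within 1.5 times or within their interval, and leaving out a library moved 41 counts and left 49.

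For single genes and exons, other settings left 786 calls the same, made 171 weaker and 47 stronger and reversed 0, and leaving out a library left 613 the same and made 239 weaker. RBMX, FAM71F1, LEXM, FAM81B and MPP4 kept their calls in NCV in all 16 settings tried, while KRTAP19-1 lost it in 3, LINC00431 and INHBE in 7, and LOC100422781, CFAP52 and ADAMTS1 in 8. Removing the minimum of 10 changed no tested gene or exon, PAR-CLIP counts by upper score were not run, and weighted PAR-CLIP calls were too few to test in the mutants.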

Other observations

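PAR-CLIP sites were also counted in other gene groups, beside a median of 2.13 sites per kb over 15888 genes. Nonsense-mediated decay targets and factors had a median of 10.3 sites per kb, led by GAS5, a snoRNA host gene, with 138 sites (33.6 per kb). Core spliceosome genes had 7.64 per kb, with 345 sites in U2AF1, S phase genes 7.88 (MCM3, a replication helicase subunit, 383 sites) and G2 and mitosis genes 7.46 (MKI67, 529 sites). Oxidative phosphorylation genes had 5.88 per kb and cholesterol synthesis genes 2.45.

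S2P peaks at the starts of p53 targets were found at 4 of 25 genes in siC, 2 in sihnG3 and 11 in sihnG4. For heat shock genes these were 9 of 19, 2 and 14, and for S phase genes 10 of 26, 2 and 16. Each count comes from 1 library per siRNA and was not tested.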
